A study of Mus musculus with 60 samples.

How the data were processed

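RNA was measured in 60 libraries from cortex, striatum and cerebellum of 3 to 4 month old female and male mice that were homozygous for a disrupted Pon2 gene (PON2-deficient) or wild-type, with 5 libraries in each of 12 groups of region, sex and genotype. The mice were littermates from heterozygous crosses on a C57BL/6J background and had been through behavioural tests. Frozen tissue was pulverised, and total RNA libraries were read as 150 nt pairs. The labels number the replicates within a group and do not state whether equal numbers in different regions come from 1 mouse.

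The deposited count table holds expected counts per gene, which are estimates and not whole numbers, for 20423 genes. Salmon, edgeR and limma are named in the submitters' processing notes, and their versions, the genome build and the annotation are not given in the sources used here. The deposited log2 values are log2 CPM as limma's voom makes them. They equal log2 of the count plus 0.5 over the TMM-scaled library size, scaled to CPM, with a largest deviation of 5.33e-14 over all genes and libraries. The deposited precision weights are a score per gene and library that the authors made with voom. They were used as weights in limma, and their mean per library as a measure of the library. All per-sample columns were used.

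Gene symbols and positions were taken from GENCODE M21 (GRCm38) by Ensembl ID. Of the 20423 gene IDs, 20403 (99.9%) matched without the version suffix and 97.7% had the same version. Library totals lay between 26.1 and 28.1 M counts (cortex 26.1 to 27.8, striatum 27.1 to 28.1, cerebellum 27.0 to 27.9), and 19941 to 20228 genes had a count in a library. At this depth 1 CPM is about 26 to 28 counts. No pair of libraries was a duplicate (highest correlation 0.989). Every library matched its labels of region, sex and genotype by marker genes.

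Counts were analysed with edgeR 4.0.16 in R 4.3.3, 1 fit per region over its 20 libraries with the means of the 4 groups of sex and genotype, TMM scaling, genes kept by filterByExpr on the groups and quasi-likelihood F tests (2-sided). Expected counts were rounded to whole numbers first, for edgeR, limma's voom and DESeq2 alike. In the deposited table each gene reached at least 9.85 counts and at least 0.365 CPM in as many libraries as a group holds, and the filter of each region kept 18972 genes in cortex, 18962 in striatum and 18710 in cerebellum. The comparisons were PON2-deficient against wild-type as the mean of both sexes and in each sex, the difference between the male and female effects, and males against females. The region comparisons took all 60 libraries and 20387 genes in 1 fit. P-values were adjusted by Benjamini and Hochberg within each comparison, with a threshold of 0.05. Log2 changes are those of the edgeR fit at its default prior count. A prior count of 2 was used only for the log2 CPM of libraries, and CPM values use TMM-scaled library sizes.

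The comparisons, the alternatives, 36 gene lists and the rule for naming genes were fixed before the data were examined. The lists held 681 genes, of which 27 were not among the 20423 genes of the deposited counts, and the filter of each region removed more. The rule names Pon2, Pon1 and Pon3, then called genes with a mean of at least 1 CPM in a genotype and a symbol that is not a predicted or clone name, the 8 largest rises and 8 largest falls in the genotype comparisons over both sexes and 4 of each elsewhere. From lists it names up to 4 called members, or 2 members with the smallest p of a list that passed as a group with no member called. Gm43610 and Gm3294 fall outside it. Lists with at least 3 tested members were tested with camera of limma 3.58.1 against all other genes with a preset correlation of 0.01, with the 35 lists adjusted together, and Pon2 was left out of every list. The paraoxonase list had too few members for this test and is given gene by gene. As alternatives the correlation was estimated from the residuals, and fry was used, which tests whether the genes of a list move one way on balance and compares them with no other gene, as well as its form for changes in either direction.

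The lists were the neighbours of Pon2 on chromosome 6, antioxidant and NRF2 target genes, coenzyme Q biosynthesis, mitochondrially encoded and nuclear respiratory genes, cytosolic ribosomal proteins, unfolded protein response, heat shock proteins, immediate early, circadian clock, glucocorticoid-induced, inflammatory and interferon-stimulated genes, and cholesterol synthesis. They also covered dopamine, GABA, glutamate and calcium genes, markers of cortical, striatal, granule, Purkinje and interneurons, and markers of astrocytes, oligodendrocytes and their precursors, microglia, vessels, meninges, ependyma, choroid plexus, thalamus, hypothalamus and red blood cells. The last were the Y-linked genes with Xist, and the paraoxonases.

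The pipeline was tested on simulated data with the spread of each region, with all libraries drawn independently. In each region 67, 67 and 66 genes, all of at least 1 CPM, were changed by 1.2-fold, 1.5-fold and 2-fold. For changes of 1.2-fold, 1.5-fold and 2-fold the share of changed genes recovered over both sexes was 55.2%, 76.1% and 100% in cortex, 17.9%, 73.1% and 90.9% in striatum and 43.3%, 76.1% and 89.4% in cerebellum. In females it was 29.9%, 64.2% and 93.9% in cortex, 2.99%, 55.2% and 84.8% in striatum and 19.4%, 58.2% and 80.3% in cerebellum. In males it was 23.9%, 64.2% and 97.0% in cortex, 2.99%, 55.2% and 80.3% in striatum and 25.4%, 64.2% and 86.4% in cerebellum. At most 5.15% of the calls in a comparison were false. The simulated cortex gave 159 calls over both sexes where the real data gave 6, and the adjusted threshold is easier to pass with more calls. Structure between libraries, such as the transcript length trend described below, was not simulated. Recovery in the real data can therefore be lower and false calls more frequent.

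The alternatives were DESeq2 1.42.0, limma's voom with quality weights, the deposited log2 values with their weights, DESeq2 size factors, no filter, a mean CPM of at least 1, 1 fit over all libraries, the replicate number as a block, 2 surrogate variables from sva 3.50.0, and each library left out in turn. Added after seeing the data were the replicate number as a block in the males of striatum, the transcript length slope or the choroid plexus marker mean of a library in the model, a robust spread in edgeR, and leaving out the libraries with a length slope under -0.1. The length slope is the slope of a library's log2 deviation from the mean of the other libraries of its region against log2 transcript length. In male striatum each of the 5 pairs of PON2-deficient and wild-type libraries with equal replicate numbers correlated above 0.1 (0.129 to 0.566). The numbers were therefore used to pair these libraries, an assumption made from the values and not from the labels. No correlations of unequal numbers are given. Replicate 5 of both genotypes had a low length slope (-0.104 and -0.335), so a shared length trend cannot be told apart from a pairing. Splits of the samples at random were drawn 100 times per comparison and 30 times for the region comparisons, for which 30 more kept equal replicate numbers of a sex and genotype together across regions.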

Results

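The effect of the loss of paraoxonase 2 (PON2), a lactonase of the mitochondrial and endoplasmic reticulum membranes, on the brain transcriptome was examined in cortex, striatum and cerebellum of PON2-deficient and wild-type mice. Each region was represented by 5 female and 5 male mice of each genotype, so that every genotype mean within a region rested on 10 libraries. Log2 changes are PON2-deficient minus wild-type, averaged over the sexes unless a sex is named, with the standard error (SE) of the edgeR fit. Expression levels are given as CPM, counts scaled to the TMM library size, with the standard deviation (SD). The p-values measure the spread between these samples.

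Pon2 (chromosome 6, positions 5264147 to 5298455 on the minus strand in GRCm38) was measured first in every library. In cortex it ranged from 48.6 to 57.1 CPM in the 10 wild-type libraries (54.0 ± 2.83, SD) and from 2.27 to 5.46 CPM in the 10 PON2-deficient libraries (3.35 ± 0.891, SD). The mean of the PON2-deficient libraries was 6.21% of wild-type in cortex, 7.53% in striatum and 1.77% in cerebellum. In striatum the ranges were 43.6 to 55.1 CPM against 2.47 to 6.72 CPM, and in cerebellum 41.2 to 54.5 CPM against 0.483 to 1.33 CPM. Pon2 fell significantly in cortex (log2 change -4.01, SE 0.0949, adjusted p = 2.66e-17), striatum (-3.74, SE 0.145, adjusted p = 1.23e-12) and cerebellum (-5.82, SE 0.120, adjusted p = 2.19e-18). The fall passed the threshold in all of the fits with 1 library left out. Pon1 was not among the tested genes. Pon3, the paralog next to Pon2, was low in all regions and was not called in any of them. It changed by -0.25 in cortex (adjusted p = 0.747), -0.02 in striatum (adjusted p = 0.996) and -1.20 in cerebellum (SE 0.303, adjusted p = 0.146), where it measured 2.57 ± 1.11 CPM in wild-type and 1.11 ± 0.641 CPM in PON2-deficient mice.

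**Figure D1:**
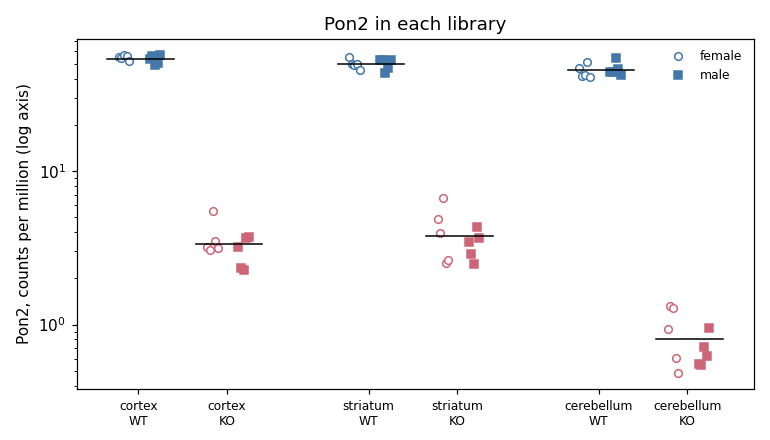
Pon2 expression in CPM (log axis) in each library of cortex, striatum and cerebellum, by genotype, with open circles for females, filled squares for males and a line at the mean of each 10 libraries. The highest PON2-deficient library (6.72 CPM, striatum) lies below the lowest wild-type library (41.2 CPM, cerebellum).

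The labels of sex and region were checked on marker genes. Xist measured 550 to 988 CPM in the 30 female libraries and 0 to 1.86 CPM in the 30 male libraries. Ddx3y measured 48.3 to 84.4 CPM in males and 0 to 0.184 CPM in females.

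To determine which transcripts change in cortex without PON2, the 20 cortex libraries were compared by genotype. Beside Pon2, 4 genes rose and 1 fell among 18972 genes tested, each by 0.28 or less on the log2 scale. Celsr3 (a cadherin of axon guidance) rose from 107 ± 9.09 to 130 ± 7.98 CPM (SD), a log2 change of 0.28 (SE 0.0464), and Slc38a2 (a neutral amino acid transporter) from 94.0 ± 7.76 to 110 ± 6.20 CPM (0.23, SE 0.0401). Rhot2, which encodes a mitochondrial GTPase, rose by 0.20 (SE 0.0351) and Capn15 by 0.17 (SE 0.0288), while the chromatin gene Hmgn2 fell from 93.6 ± 6.29 to 82.0 ± 3.05 CPM (-0.19, SE 0.0329). The adjusted p of these 5 genes was 0.0351. At an unadjusted p under 0.05, 2159 genes passed in edgeR, and DESeq2 called 238 genes where edgeR called 6. edgeR called 127 with the transcript length slope of each library in the model, 24 with the replicate number as a block, and 2 with the choroid plexus marker mean in the model or in 1 fit over all libraries, while limma with quality weights called 34. The choroid plexus mean ended the calls of Slc38a2, Rhot2, Capn15 and Hmgn2, 2 surrogate variables those of Slc38a2, Rhot2 and Hmgn2, the deposited values and weights those of Rhot2 and Hmgn2, and the fit over all libraries those of all 5. The calls of Celsr3, Slc38a2, Rhot2, Capn15 and Hmgn2 ended in 10, 15, 14, 13 and 13 of the 20 fits with 1 library left out, and the count moved with most libraries. It was 1 without wild-type female 5, male 2 or male 4 or without PON2-deficient female 1, female 2, male 1 or male 2, 2 without wild-type male 5 or PON2-deficient female 3 or male 3, and 3 without wild-type female 2 or PON2-deficient female 4 or male 5. It was 10 without PON2-deficient male 4, 11 without wild-type female 1, 12 without wild-type male 1, 22 without wild-type male 3 and 26 without PON2-deficient female 5.

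Among the 35 gene lists tested in cortex, 15 passed with the preset correlation, 6 upward and 9 downward, 0 with an estimated correlation and 1 in fry. In these 15 lists edgeR called 0 members over all genes in this comparison. Of the 23 immediate early genes, 20 were higher (median log2 0.29, 1 called adjusted over the list alone, adjusted p = 1.36e-08, and adjusted p = 0.435 with an estimated correlation). Of the 16 heat shock proteins, 15 were higher (median log2 0.067, 0 called adjusted over the list alone, adjusted p = 0.00351, and adjusted p = 0.435 with an estimated correlation). Of the 16 circadian clock genes, 13 were higher (median log2 0.041, 3 called adjusted over the list alone, adjusted p = 0.00425, and adjusted p = 0.435 with an estimated correlation). Of the 13 glucocorticoid-induced genes, 11 were higher (median log2 0.085, 0 called adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.435 with an estimated correlation). Of the 22 genes of cholesterol synthesis, 19 were higher (median log2 0.033, 1 called adjusted over the list alone, adjusted p = 0.00328, and adjusted p = 0.444 with an estimated correlation). Of the 30 genes of calcium channels, stores and pumps, 21 were higher (median log2 0.049, 0 called adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.435 with an estimated correlation). The members nearest to a call were Per2 (0.39, SE 0.0772, adjusted p = 0.0550) and Cyp51 (0.28, SE 0.0600, adjusted p = 0.0652). Leaving out PON2-deficient female 5 ended the call of the clock list (adjusted p = 0.0621) and left 9 lists called, and leaving out PON2-deficient female 3 that of the cholesterol list (0.0721). The calls of the glucocorticoid and calcium lists ended in 10 and 14 of the 20 such fits, and both ended with the choroid plexus mean or 2 surrogate variables in the model. The surrogate variables also ended the call of the heat shock list, and the length slope that of the calcium list (adjusted p = 0.948).

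The lower lists in cortex held nuclear respiratory, ribosomal and antioxidant genes, the neighbours of Pon2 and microglia markers. The others were named for tissue outside the cortex. Of the 41 nuclear respiratory chain genes, 37 were lower (median log2 -0.038, 1 called adjusted over the list alone, adjusted p = 2.68e-05, and adjusted p = 0.435 with an estimated correlation). Of the 37 cytosolic ribosomal proteins, 36 were lower (median log2 -0.045, 0 called adjusted over the list alone, adjusted p = 5.11e-06, and adjusted p = 0.435 with an estimated correlation). Of the 28 antioxidant and NRF2 target genes, 22 were lower (median log2 -0.057, 0 called adjusted over the list alone, adjusted p = 0.000946, and adjusted p = 0.435 with an estimated correlation). Of the 31 neighbours of Pon2 on chromosome 6, 26 were lower (median log2 -0.055, 2 called adjusted over the list alone, adjusted p = 0.00277, and adjusted p = 0.138 with an estimated correlation). Cox7c was nearest to a call (-0.16, SE 0.0330, adjusted p = 0.0652). In fry the list of Pon2 neighbours passed with adjusted p = 0.0168. With the transcript length slope in the model the calls of the nuclear respiratory (adjusted p = 0.577), ribosomal (0.442) and antioxidant (0.445) lists ended. This slope, whose cause was not tested, moved with genotype in male cortex, from -0.0742 to 0.00700 in the 5 wild-type and from -0.00754 to 0.0314 in the 5 PON2-deficient libraries.

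The lists named for choroid plexus, ependyma, hypothalamus and thalamus, and the microglia list, were lower as well. Of the 22 choroid plexus markers, 22 were lower (median log2 -0.81, 0 called adjusted over the list alone, adjusted p = 2.10e-06, and adjusted p = 0.435 with an estimated correlation). Of the 14 ependymal markers, 14 were lower (median log2 -0.30, 4 called adjusted over the list alone, adjusted p = 4.15e-06, and adjusted p = 0.209 with an estimated correlation). Of the 9 hypothalamic and pituitary peptides, 6 were lower (median log2 -0.50, 0 called adjusted over the list alone, adjusted p = 0.0309, and adjusted p = 0.435 with an estimated correlation). Of the 12 thalamic markers, 9 were lower (median log2 -0.12, 1 called adjusted over the list alone, adjusted p = 0.0488, and adjusted p = 0.435 with an estimated correlation). Of the 18 microglia markers, 15 were lower (median log2 -0.045, 0 called adjusted over the list alone, adjusted p = 0.0462, and adjusted p = 0.444 with an estimated correlation). The mean log2 CPM of the choroid plexus markers ranged from 0.35 to 3.19 among the cortex libraries. Foxj1 was lower by -0.41 (SE 0.106, adjusted p = 0.115) and Aqp1 by -1.34 (SE 0.395, adjusted p = 0.174). Calb2, the thalamic list member with the lowest p, changed by -0.73 (SE 0.215, adjusted p = 0.167). Which cells these transcripts come from was not tested. The calls of the hypothalamic, thalamic and microglia lists ended in 10, 12 and 9 of the 20 fits with 1 library left out, and all 3 ended with the choroid plexus mean in the model. The length slope or 2 surrogate variables ended those of the hypothalamic and thalamic lists. For the other 20 lists adjusted p and median log2 are given as a pair. Nearest to the threshold were the genes of GABA synthesis, transport and reception (0.0635, -0.025), the genes of dopamine signalling (0.0811, -0.028), the cortical excitatory neuron markers (0.0811, 0.044), the endothelial and mural markers (0.111, 0.032) and the cerebellar granule neuron markers (0.163, -0.037). Next came the Purkinje neuron markers (0.163, -0.041), the interneuron markers (0.173, -0.036), the Y-linked genes and Xist (0.304, 0.13), the genes of the unfolded protein response (0.309, 0.032) and the mitochondrially encoded respiratory genes (0.472, 0.023). Further from it were the interferon-stimulated genes (0.494, 0.023), the oligodendrocyte precursor markers (0.563, 0.048), the meningeal fibroblast markers (0.618, -0.029), the red blood cell markers (0.691, -0.042) and the oligodendrocyte and myelin markers (0.737, 0.00029). The last were the inflammatory and NF-kB target genes (0.858, 0.037), the striatal projection neuron markers (0.858, -0.0087), the genes of coenzyme Q biosynthesis (0.972, 0.0017), the astrocyte markers (0.972, -0.015) and the glutamate receptors (0.992, -0.0014). Median and mean differed in sign for the inflammatory list (0.037 and -7.0e-05), the myelin list (0.00029 and -0.011), the oligodendrocyte precursor list (0.048 and -0.0022) and the red blood cell list (-0.042 and 0.053).

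In striatum the genotypes differed in 2 of 18962 genes, Pon2 and Gm43610. Gm43610, a predicted gene on chromosome 5 that was chosen after its values were seen, rose from 0.0329 ± 0.0270 to 0.366 ± 0.163 CPM (SD), a log2 change of 3.31 (SE 0.428, adjusted p = 0.00178). Both calls held in all 20 fits with 1 library left out. edgeR passed 937 genes at an unadjusted p under 0.05, and DESeq2 called 7 genes. edgeR called 4 genes with the replicate number as a block in the males, and 4 in 1 fit over all libraries. The spread between libraries was larger here than elsewhere (biological coefficient of variation 0.187, against 0.120 in cortex and 0.128 in cerebellum). On simulated data of this spread, with more changed genes than were called here, 17.9% of genes with a 1.2-fold change were recovered.

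As a group, the mitochondrially encoded respiratory genes were lower in PON2-deficient striatum over both sexes. Of the 13 mitochondrially encoded respiratory genes, 12 were lower (median log2 -0.19, 7 called adjusted over the list alone, adjusted p = 3.87e-12, and adjusted p = 0.0367 with an estimated correlation). With an estimated correlation it did not pass in females (adjusted p = 0.280) or in males (0.0867, or 0.0986 with the replicate numbers as a block in males). In fry its adjusted p was 0.0238 over both sexes, and 0.116 in the form of fry that takes changes in either direction. With the preset correlation and the transcript length slope in the model its adjusted p was 1.97e-16. Neither this model nor the fits with 1 library left out were run with an estimated correlation for this list. The slope moved with genotype in female striatum, from -0.0183 to 0.0182 in the 5 wild-type and from 0.0253 to 0.0491 in the 5 PON2-deficient libraries. Whether the call with an estimated correlation depends on it was not tested. mt-Nd5 measured 4146 ± 303 CPM in wild-type and 3539 ± 441 CPM in PON2-deficient libraries (SD), a change of -0.23 (SE 0.0649, adjusted p = 0.713), and mt-Cytb changed by -0.19 (SE 0.0538, adjusted p = 0.720). Of the 35 lists, 7 passed with the preset correlation, 3 upward and 4 downward, 1 with an estimated correlation and 1 in fry, while edgeR called 0 of their members over all genes. Of the 23 immediate early genes, 20 were higher (median log2 0.31, 9 called adjusted over the list alone, adjusted p = 8.20e-13, and adjusted p = 0.175 with an estimated correlation). Of the 15 ependymal markers, 14 were higher (median log2 0.34, 4 called adjusted over the list alone, adjusted p = 7.08e-08, and adjusted p = 0.466 with an estimated correlation). Of the 13 thalamic markers, 12 were lower (median log2 -0.36, 0 called adjusted over the list alone, adjusted p = 2.38e-06, and adjusted p = 0.466 with an estimated correlation). Of the 19 cortical excitatory neuron markers, 14 were lower (median log2 -0.081, 0 called adjusted over the list alone, adjusted p = 0.0479, and adjusted p = 0.913 with an estimated correlation). Of the 37 cytosolic ribosomal proteins, 35 were higher (median log2 0.13, 0 called adjusted over the list alone, adjusted p = 5.64e-06, and adjusted p = 0.959 with an estimated correlation). Of the 30 genes of calcium channels, stores and pumps, 27 were lower (median log2 -0.054, 0 called adjusted over the list alone, adjusted p = 0.00289, and adjusted p = 0.913 with an estimated correlation). Nr4a3 changed by 0.82 (SE 0.214, adjusted p = 0.705) and Egr1 by 0.44 (SE 0.133, adjusted p = 0.733). Without PON2-deficient male 5 the ribosomal list turned downward (adjusted p = 0.745) and the calcium list lost its call (0.769), and the nuclear respiratory list, not called with it, was lower (adjusted p = 1.86e-07). The call of the calcium list also ended with 2 surrogate variables, and that of the cortical list with each alternative model run. The count of lists was 12 without PON2-deficient female 5 and 11 without PON2-deficient male 3, and the call of the cortical list ended in 11 of the 20 fits.

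One striatum library, PON2-deficient male 5, stood apart from the others. Its mean deposited precision weight was 0.0527 of the median of the striatum libraries, and it had 19941 genes with a count, the fewest of the 60 libraries. The slope of its log2 deviation against log2 transcript length was -0.335. For the other 28 lists adjusted p and median log2 are given as a pair. Nearest to the threshold were the heat shock proteins (0.0826, 0.076), the glutamate receptors (0.179, -0.040), the genes of GABA synthesis, transport and reception (0.182, -0.054), the red blood cell markers (0.182, 0.13) and the genes of dopamine signalling (0.220, -0.045). Next came the oligodendrocyte and myelin markers (0.298, 0.058), the microglia markers (0.310, -0.020), the nuclear respiratory chain genes (0.341, 0.059), the genes of the unfolded protein response (0.364, 0.055) and the interneuron markers (0.455, 0.0050). Further from it were the striatal projection neuron markers (0.461, -0.025), the circadian clock genes (0.493, -0.045), the genes of cholesterol synthesis (0.566, 0.040), the neighbours of Pon2 on chromosome 6 (0.599, -0.022) and the choroid plexus markers (0.599, -0.0028). Then came the oligodendrocyte precursor markers (0.599, 0.053), the Y-linked genes and Xist (0.599, 0.054), the astrocyte markers (0.613, -0.012), the inflammatory and NF-kB target genes (0.629, 0.043) and the glucocorticoid-induced genes (0.638, 0.0016). Further still were the cerebellar granule neuron markers (0.638, -0.023), the interferon-stimulated genes (0.840, -0.0017), the Purkinje neuron markers (0.868, -0.023), the genes of coenzyme Q biosynthesis (0.954, 0.011) and the antioxidant and NRF2 target genes (0.993, 0.011). The last were the hypothalamic and pituitary peptides (0.993, -0.038), the endothelial and mural markers (0.993, 0.0079) and the meningeal fibroblast markers (0.993, 0.0011). Median, mean and the direction of the test did not share a sign for the interferon, Purkinje, hypothalamic, astrocyte, endothelial, meningeal and interneuron lists, where medians lay between -0.038 and 0.0079.

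In cerebellum 2 genes rose and 4 fell among 18710 genes tested, Pon2 among the latter. Usp19 (a deubiquitinase of the endoplasmic reticulum) rose from 158 ± 6.40 to 187 ± 13.0 CPM (SD), a log2 change of 0.24 (SE 0.0390, adjusted p = 0.0231). Rara (retinoic acid receptor alpha) fell from 20.9 ± 1.37 to 17.1 ± 2.30 CPM (-0.30, SE 0.0525, adjusted p = 0.0421) and Zfp811 from 14.5 ± 1.27 to 11.4 ± 0.953 CPM (-0.34, SE 0.0563, adjusted p = 0.0231). Asb4, a gene next to Pon2, fell from 1.27 ± 0.442 to 0.429 ± 0.240 CPM (-1.55, SE 0.269, adjusted p = 0.0421). Gm3294, a predicted gene chosen after its values were seen, rose by 0.50 (SE 0.0753, adjusted p = 0.0161) from 17.9 to 25.1 CPM. edgeR passed 2081 genes at an unadjusted p under 0.05, DESeq2 called 244 genes and limma with quality weights 23. edgeR called 13 in 1 fit over all libraries, 11 with the replicate number as a block and 10 with 2 surrogate variables. The fit over all libraries ended the calls of Usp19, Asb4, Zfp811 and Rara, the choroid plexus mean those of Usp19 and Asb4, DESeq2 that of Asb4, 2 surrogate variables that of Usp19, and the length slope, no filter or leaving out the library with a low length slope that of Rara. The calls of Usp19, Asb4, Zfp811, Rara and Gm3294 ended in 7, 11, 6, 14 and 2 of the 20 fits with 1 library left out. The count of genes was 1 without wild-type female 4 or male 5, 2 without wild-type female 2, male 1 or male 2, and 3 without PON2-deficient female 1, male 2 or male 5. It was 13 without PON2-deficient male 3, 15 without PON2-deficient male 1 and 49 without wild-type male 3.

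Of the 35 lists, 8 passed in cerebellum with the preset correlation, 2 upward and 6 downward, and 0 with an estimated correlation or in fry. edgeR called 0 members of these lists over all genes. Of the 13 mitochondrially encoded respiratory genes, 13 were lower (median log2 -0.11, 10 called adjusted over the list alone, adjusted p = 6.89e-10, and adjusted p = 0.368 with an estimated correlation). Of the 28 antioxidant and NRF2 target genes, 19 were lower (median log2 -0.043, 0 called adjusted over the list alone, adjusted p = 0.0319, and adjusted p = 0.680 with an estimated correlation). Of the 22 immediate early genes, 15 were higher (median log2 0.20, 2 higher and 1 lower called adjusted over the list alone, adjusted p = 0.00911, and adjusted p = 0.718 with an estimated correlation). Of the 22 interferon-stimulated genes, 19 were higher (median log2 0.16, 1 called adjusted over the list alone, adjusted p = 0.0136, and adjusted p = 0.804 with an estimated correlation). Of the 5 Y-linked genes and Xist, 4 were lower (median log2 -0.24, 1 called adjusted over the list alone, adjusted p = 0.0426, and adjusted p = 0.368 with an estimated correlation). Nearest to a call were mt-Nd6 (-0.30, SE 0.0550, adjusted p = 0.0574) and Ier5 (-0.27, SE 0.0516, adjusted p = 0.0641), which was lower while most immediate early genes were higher. Xist changed by -1.24 (SE 0.251, adjusted p = 0.0641), a value that rests on male libraries near 0. The call of the immediate early list ended without wild-type female 4 (adjusted p = 0.0742) or wild-type male 4 (0.0550). The calls of the antioxidant, interferon and Y-linked lists ended in 7, 5 and 11 of the 20 such fits, and all 3 ended with the choroid plexus mean in the model. With 2 surrogate variables the antioxidant, immediate early and interferon lists lost their calls, and with the replicate block the Y-linked list.

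Markers of meninges, choroid plexus and ependyma were lower in PON2-deficient cerebellum. Of the 17 meningeal fibroblast markers, 17 were lower (median log2 -0.19, 2 called adjusted over the list alone, adjusted p = 6.08e-06, and adjusted p = 0.410 with an estimated correlation). Of the 22 choroid plexus markers, 22 were lower (median log2 -0.35, 0 called adjusted over the list alone, adjusted p = 7.25e-06, and adjusted p = 0.718 with an estimated correlation). Of the 15 ependymal markers, 13 were lower (median log2 -0.15, 0 called adjusted over the list alone, adjusted p = 0.00852, and adjusted p = 0.702 with an estimated correlation). Dcn was nearest to a call (-0.33, SE 0.0651, adjusted p = 0.0641). The mean log2 CPM of the choroid plexus markers was 0.65 in PON2-deficient female 5 and 0.70 in PON2-deficient male 4. It was between 3.24 and 5.21 in the other PON2-deficient libraries, and between 3.32 and 5.07 in wild-type. The lower choroid plexus list can thus rest on these 2 libraries, and no fit without both was made. Without PON2-deficient female 5 the call of the ependymal list ended (adjusted p = 0.0519) and 4 lists were called, and without wild-type female 4 there were 5. With 2 surrogate variables the choroid plexus and ependymal lists lost their calls. For the other 27 lists adjusted p and median log2 are given as a pair. Nearest to the threshold were the microglia markers (0.0752, -0.065), the neighbours of Pon2 on chromosome 6 (0.0903, -0.025), the red blood cell markers (0.0903, -0.13), the astrocyte markers (0.0991, -0.049) and the endothelial and mural markers (0.0991, -0.053). Next came the striatal projection neuron markers (0.241, -0.044), the genes of cholesterol synthesis (0.250, 0.040), the genes of dopamine signalling (0.250, -0.039), the Purkinje neuron markers (0.255, -0.023) and the thalamic markers (0.255, -0.044). Further from it were the heat shock proteins (0.300, 0.052), the glucocorticoid-induced genes (0.300, 0.098), the circadian clock genes (0.375, 0.0062), the nuclear respiratory chain genes (0.402, 0.0023) and the cytosolic ribosomal proteins (0.503, -0.016). Then came the glutamate receptors (0.503, -0.011), the genes of calcium channels, stores and pumps (0.503, 0.00095), the cerebellar granule neuron markers (0.503, -0.043), the oligodendrocyte precursor markers (0.503, 0.023) and the interneuron markers (0.503, 0.0074). Further still were the hypothalamic and pituitary peptides (0.540, 0.25), the oligodendrocyte and myelin markers (0.622, 0.032), the genes of the unfolded protein response (0.700, 0.030), the genes of GABA synthesis, transport and reception (0.700, 0.0079) and the cortical excitatory neuron markers (0.762, 0.012). The last were the inflammatory and NF-kB target genes (0.799, 0.0092) and the genes of coenzyme Q biosynthesis (0.883, -0.0021). Median, mean and the direction of the test did not share a sign for the coenzyme Q, inflammatory, cortical and interneuron lists, where medians lay between -0.0021 and 0.012.

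To determine whether the genotype effect depends on sex, females and males were compared by genotype within each region and the effects were tested against each other. In female mice Pon2 was the only gene called in the edgeR fit of each region, with log2 changes of -3.90 (SE 0.133, adjusted p = 4.32e-14) in cortex, -3.59 (SE 0.202, adjusted p = 1.80e-09) in striatum and -5.58 (SE 0.167, adjusted p = 3.85e-15) in cerebellum. In 1 fit over all libraries edgeR called 4 genes in female cortex and 18 in female striatum, and DESeq2 called 31, 2 and 8 in the 3 regions. In male cortex 21 genes rose and 7 fell. Per2 rose from 24.1 ± 4.49 to 38.6 ± 4.52 CPM (0.68, SE 0.110, adjusted p = 0.0176) and Frmd6 from 34 ± 6.44 to 54.4 ± 8.20 CPM (0.68, SE 0.125, adjusted p = 0.0329). Vipr1 (0.64, adjusted p = 0.0495) and Map3k13 (0.49, adjusted p = 0.0165) rose too. Uqcr11, a subunit of respiratory complex III, fell from 105 ± 6.24 to 84.2 ± 4.06 CPM (-0.31, SE 0.0491, adjusted p = 0.0165), and Hmgn2 fell by 0.25 on the log2 scale (adjusted p = 0.0337). Rps27rt (-0.33, adjusted p = 0.0329) is a retrotransposed copy of a ribosomal gene, so its reads are uncertain. With the transcript length slope in the model, which moved with genotype in male cortex as given above, the calls of Uqcr11, Rps27rt, Hmgn2 and Vipr1 ended. With 2 surrogate variables those of Per2, Frmd6, Vipr1, Map3k13, Hmgn2 and Rps27rt ended and 5 genes were called. In 1 fit over all libraries those of Frmd6, Uqcr11, Rps27rt, Hmgn2 and Vipr1 ended and 17 genes were called, and in limma with quality weights or with the deposited values and weights those of Hmgn2 and Vipr1. Vipr1 was also lost with no filter or a robust spread. In male cerebellum Rara fell by 0.48 on the log2 scale (adjusted p = 0.0136), one of 3 genes called there, a call that ended in 1 fit over all libraries and without the library with a low length slope. The male cerebellum count was 203 in DESeq2, 14 in the fit over all libraries, 12 in limma with quality weights, 7 with the length slope in the model and 5 with the replicate block. In male striatum Pon2 was the only gene called in the fit of the region (-3.89, SE 0.206, adjusted p = 5.69e-10), while 11 genes were called in 1 fit over all libraries, 5 in DESeq2 and 2 in limma with quality weights.

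The effects of the sexes were then set against each other. edgeR called 0 genes for the difference between the male and female genotype effects in each region, with 1814 genes at an unadjusted p under 0.05 in cortex, 818 in striatum and 885 in cerebellum. DESeq2 called 51, 7 and 1 genes, and limma with quality weights 0, 0 and 0. With the replicate number as a block edgeR called 3 genes for this difference in cortex, and in 1 fit over all libraries 6 in striatum. In the female comparisons the numbers at an unadjusted p under 0.05 were 1252, 774 and 965, and in the male comparisons 2657, 1130 and 1988. Across genes, which are not independent replicates, the female and male log2 changes had Pearson correlations of 0.0974 in cortex, -0.0201 in striatum and 0.0872 in cerebellum.

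The male cortex count depended on single libraries and was 433 in DESeq2. It was 150 without wild-type male 4 and 1 without PON2-deficient male 3, 5 without wild-type male 5 and 7 without PON2-deficient male 5. It was 8 without PON2-deficient male 1, 9 without wild-type male 2 or PON2-deficient male 4, 10 without wild-type female 3 or PON2-deficient female 3, and 14 without wild-type male 3. The interaction count in cortex was 1 without wild-type female 3 or PON2-deficient male 2 and 2 without PON2-deficient female 5. In male cerebellum the count was 5 without wild-type female 4, 6 without PON2-deficient female 4, female 5 or male 1, 7 without wild-type male 1 and 41 without wild-type male 3. In females the count was 2 without PON2-deficient female 4 in cortex, without PON2-deficient male 4 or male 5 in striatum, and without wild-type male 4 in cerebellum.

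In striatum the genotype effect on the oligodendrocyte and myelin markers differed between the sexes. Of the 20 markers, 20 were lower in PON2-deficient females (adjusted p = 1.97e-10, and adjusted p = 0.138 with an estimated correlation) and 20 were higher in PON2-deficient males (adjusted p = 3.72e-14, and adjusted p = 0.0807 with an estimated correlation). The interaction (median log2 0.44) passed with adjusted p = 6.78e-24, with adjusted p = 0.00839 with an estimated correlation, and with adjusted p = 0.00412 in fry. With the replicate numbers as a block in males, a pairing assumed from the values, the list passed with adjusted p = 1.06e-21 and in fry (0.0169). With this block and an estimated correlation its call ended (adjusted p = 0.0682). Adjusted over the list alone, 14 of the 20 markers passed for the interaction, and 0 over all genes. Cnp changed by -0.30 in females and 0.19 in males, Cldn11 by -0.22 and 0.24, Mbp by -0.17 and 0.33, and Mog by -0.26 and 0.30. The mean log2 CPM of the list was 7.49 ± 0.108 (SD, n = 5) in wild-type females, 7.32 ± 0.0852 in PON2-deficient females, 7.11 ± 0.0253 in wild-type males and 7.34 ± 0.109 in PON2-deficient males. Wild-type females and males were thus further apart than the PON2-deficient ones. Over the 3 regions, 105 list tests of this interaction were made. With the preset correlation 9 lists passed in cortex, 8 in striatum and 4 in cerebellum, and with an estimated correlation 0, 1 and 0, the 1 list being lost with the block in males. The other lists with a higher male than female effect in striatum were the nuclear respiratory (adjusted p = 3.05e-11, and adjusted p = 0.546 with an estimated correlation), ribosomal (2.93e-10, 0.546), thalamic (1.71e-05, 0.464), glucocorticoid (0.00168, 0.464), antioxidant (0.00399, 0.546) and oligodendrocyte precursor lists (0.00535, 0.239), and the calcium list had a lower one (4.63e-05, 0.546). PON2-deficient male 5 stood apart in the nuclear respiratory and ribosomal lists. Its mean log2 CPM of the nuclear respiratory list was 7.846, against 6.896 to 6.997 in the other PON2-deficient males. For the ribosomal list it was 8.716, against 7.558 to 7.701. Whether the interactions of these lists pass without this library is not shown here.

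**Figure D2:**
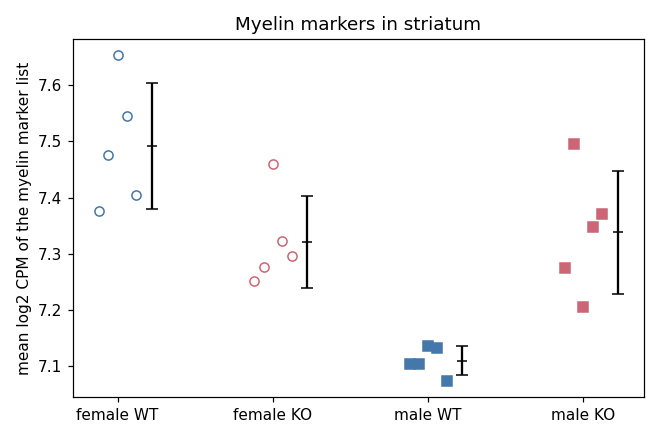
Mean log2 CPM of the 20 oligodendrocyte and myelin markers in each striatum library by sex and genotype, with the mean ± SD of each group of 5. The 5 wild-type male libraries lie between 7.07 and 7.14, and the 5 wild-type female libraries between 7.38 and 7.65.

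Males differed from females in 17 genes in cortex (10 higher, 7 lower), 20 in striatum (12 higher, 8 lower) and 22 in cerebellum (8 higher, 14 lower). DESeq2 called 80, 59 and 44 genes, limma with quality weights 57 in striatum, and edgeR in 1 fit over all libraries 145 in striatum. In cortex edgeR called 11 with the replicate block or the length slope and 10 with the choroid plexus mean in the model. The Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty were higher and Xist lower in males in each region, for Xist by -9.95 in cortex (SE 0.184), -10.65 in striatum (SE 0.152) and -10.97 in cerebellum (SE 0.169). The X-linked genes Eif2s3x (-0.60 in cortex, SE 0.0246, adjusted p = 3.51e-13) and Kdm6a (-0.44, SE 0.0828, adjusted p = 0.0452) were lower in males in cortex and in striatum, and Ddx3x (-0.37, SE 0.0375, adjusted p = 5.64e-06) in cortex. Only the 4 largest falls of a region were named, so a gene not named for a region may still have been called there. The call of Kdm6a in cortex ended with the length slope or the choroid plexus mean in the model. Ankub1 was lower in male striatum (-0.61, SE 0.107, adjusted p = 0.0217). Zfp459 (-1.25, adjusted p = 0.0436), Prl2c2 (-1.23, adjusted p = 0.0126) and Prl2c3 (-1.12, adjusted p = 6.99e-05) were lower in male cerebellum, and the last pair are close copies that share reads. The call of Zfp459 ended in limma with quality weights and with the deposited values and weights. Of the 35 lists, 9 passed for sex in cortex, 14 in striatum and 6 in cerebellum with the preset correlation, and 1, 3 and 1 with an estimated correlation. Among them, 8 of 8 red blood cell markers were higher in male striatum (median log2 0.76, adjusted p = 2.14e-13, and adjusted p = 0.0250 with an estimated correlation). With an estimated correlation this list did not pass in cortex (8 of 9 higher, median log2 0.78, adjusted p = 2.57e-09, and adjusted p = 0.0659 with an estimated correlation) or cerebellum (8 of 9, 0.57, adjusted p = 0.00141, and adjusted p = 0.645 with an estimated correlation). In striatum 12 of 13 oligodendrocyte precursor markers were lower in males (median log2 -0.17, adjusted p = 7.10e-05, and adjusted p = 0.0250 with an estimated correlation). In cortex the count of genes was 9 to 11 without any 1 of wild-type females 1, 2, 4 or 5, wild-type males 2, 3 or 5, or PON2-deficient females 1 or 4 or males 2 or 4. In striatum it was 11 without wild-type female 3, and 10 without wild-type female 4 or PON2-deficient female 2.

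To test whether the effect of PON2 loss differs between regions, the genotype effects were compared over 20387 genes in a fit of all 60 libraries. Pon2 fell further in cerebellum than in cortex (difference -1.81, adjusted p = 1.66e-08) and than in striatum (-2.09, adjusted p = 8.47e-11). For Gm43610 the genotype effect was lower in cerebellum than in cortex (-4.16, adjusted p = 3.41e-05) and in striatum (-3.18, adjusted p = 1.47e-05). Within its region Gm43610 was not tested in cortex and not called in cerebellum (0.14, adjusted p = 0.762), and these differences rest on values near 0, such as the wild-type mean of 0.0329 CPM in striatum. Xist differed between cerebellum and cortex (-2.02, adjusted p = 0.00277), a value that rests on male libraries near 0 and was not called in limma with quality weights (adjusted p = 0.180) or with the deposited values and weights (0.140). These were the 3 genes called between cerebellum and cortex and the 2 between cerebellum and striatum, with 846 and 1217 genes at an unadjusted p under 0.05. DESeq2 called 17 and 7, and limma with quality weights 12 between cerebellum and cortex. With a block for each sex, genotype and number, which takes equal numbers across regions as 1 mouse, edgeR called 4 and 3, these genes among them. Between striatum and cortex edgeR called 0 genes, with 1285 at an unadjusted p under 0.05, DESeq2 called 7 and limma with quality weights 0. The count between striatum and cortex was 1 without striatum wild-type female 5 or male 3 and 2 without striatum PON2-deficient male 1. Between cerebellum and cortex it was 5 without striatum PON2-deficient male 5 or cerebellum wild-type male 3.

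Pon2 was the only gene called in 2 regions by edgeR, and it was called in all 3. Across genes, which are not independent replicates, the log2 changes had a Pearson correlation of 0.0427 between cortex and striatum, 0.135 between cortex and cerebellum (Spearman 0.260) and 0.160 between striatum and cerebellum. With the calls of DESeq2, 24 genes were shared between cortex and cerebellum, and no number expected by chance is given for this overlap. The best match of a library in the other region had its own replicate number in 16 of 20 for cerebellum and cortex. It did so in 14 for cerebellum and striatum and 9 for striatum and cortex, where chance gives 4. The regions may thus share mice, and differences between mice other than genotype could recur in each region. The correlations and the shared genes therefore cannot be read as agreement between independent samples.

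Because the mutant allele can carry a linked stretch of its strain of origin, calls were counted around Pon2. In cerebellum 1 of 76 genes within 20 Mb was called (Asb4) against 4 of 18614 elsewhere (Fisher's exact test, 2-sided, p = 0.0202), and the exact p was 0.00906 within 5 Mb, 0.0122 within 10 Mb and 0.0229 over chromosome 6, where Gm3294 lies too. This test rests on 1 gene. In cortex edgeR called 0 of 86 genes within 20 Mb and in striatum 0 of 86, with 9 and 3 of them at an unadjusted p under 0.05. With the calls of DESeq2 in cortex, 4 genes lay within 20 Mb (exact p = 0.0228). In cortex Asb4 changed by -1.11 (SE 0.309, adjusted p = 0.146) and Calcr by -1.42 (SE 0.386, adjusted p = 0.139), from wild-type means of 1.24 and 1.38 CPM.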

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

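The tests of the 3 patterns weighed here, of striatum PON2-deficient male 5, of the myelin markers and of the neighbours of Pon2, were chosen only after the result was seen; the random splits of the samples were planned, and those without Pon2, within male pairs or with equal numbers kept together were not. In groups of 4 to 10 libraries, a library was singled out when its gap to the nearest other was more than 0.71 of the range of its group of 5. Chance singles out about 1 in 20 groups, or 4.6 of the 92 groups examined, and 12 were found.

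Total counts stood apart in cortex PON2-deficient male 2 (26.1 M counts), striatum wild-type male 5 (28.1 M counts) and cerebellum wild-type male 1 (27.4 M counts). The transcript length slope stood apart in cortex wild-type female 4 (0.0516), striatum wild-type male 5 (-0.104), striatum PON2-deficient male 5 (-0.335) and cerebellum wild-type male 4 (-0.116). Among named genes, Pon2 measured 5.46 CPM in cortex PON2-deficient female 3, Rhot2 75.7 CPM in cortex PON2-deficient female 2 and Capn15 53.8 CPM in cortex PON2-deficient male 3. Gm43610 measured 0 CPM in striatum wild-type female 2, and Usp19 165 CPM in cerebellum PON2-deficient female 3.

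Genotype effects differed between groups in a test of the difference for 6 results. Cerebellum minus cortex, the effect differed by -1.81 for Pon2, -4.16 for Gm43610 and -2.02 for Xist. Cerebellum minus striatum, it differed by -2.09 for Pon2 and -3.18 for Gm43610. In striatum the male minus female effect on the myelin markers was 0.44 (median log2, adjusted p = 0.00839 with an estimated correlation). With the male pairs as a block this last call ended (adjusted p = 0.0682), while it passed with the preset correlation (1.06e-21).

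The real split of the libraries was compared with random splits, 100 per comparison with the real one included. For the genotype in both sexes, with Pon2 left out as the disrupted gene, few splits reached the number of genes in cortex (5 real, highest other 13, 2 splits as high), striatum (1 real, highest other 0, 1 as high) and cerebellum (5 real, highest other 4, 1 as high), and so it was in male cortex (27 real, highest other 20, 1 as high). With Pon2 counted, the real numbers were 6, 2, 6 and 28, and 2, 1, 1 and 1 splits were as high. Chance is thus a less likely source of these numbers but is not excluded, since the shares were not adjusted for the number of comparisons. The 1 gene in striatum was Gm43610, near 0 CPM, and these splits did not keep the male pairs. The counts in cortex also moved with single libraries left out. In male cerebellum the number without Pon2 was reached by more splits (2 real, highest other 3, 6 as high), and with Pon2 by 2 (3 real), so chance stays open there. In female cortex, striatum and cerebellum and in male striatum Pon2 was the only call, so that the splits decide nothing on other genes. The real number with Pon2 was 1 in each, 2, 11, 2 and 5 splits were as high (highest other 1, 4, 1 and 1), and 100 of 100 splits reach the 0 without it. The interaction counts of 0 are likewise reached by 100 of 100 splits (highest other 3 in cortex, 11 in striatum and 4 in cerebellum), which decides nothing. The splits that part all 5 male pairs of striatum are 16, too few for a share under 0.05, with 1 gene in males and 0 for the interaction in the real split and at most 0 and 1 in the others, which exchange labels within pairs.

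For the number of gene lists chance cannot be excluded, with 15 real in cortex (highest other 19, 10 as high), 7 in striatum (highest other 20, 83 as high) and 8 in cerebellum (highest other 18, 62 as high). For male against female only the real split reached the count in cortex (17 real, highest other 5), striatum (20 real, highest other 1) and cerebellum (22 real, highest other 1), each with 1 split as high. These counts hold the Y-linked genes and Xist, which true labels of sex must call. No splits were counted without them, so the splits decide nothing on other genes. Of 30 splits for the region comparisons, 30 reach the count of 0 between striatum and cortex (highest other 185), which decides nothing. Between cerebellum and cortex only the real split reached the count (3 real, 2 without Pon2, highest other 1, 1 split as high for both). Beside Pon2 the genes called were Gm43610 and Xist, which rest on values near 0, so the 30 splits do not show an effect on other genes. Between cerebellum and striatum more splits reached the count (2 real, 3 as high, and 1 real without Pon2, 6 as high, highest other 23), and chance stays open. These splits redrew the labels in each region apart. With equal numbers kept together across regions in 30 further splits, the result was the same without Pon2, between cerebellum and cortex (2 real, highest other 1, 1 split as high) and between cerebellum and striatum (1 real, highest other 2, 6 as high). The 185 genes came from 1 of the 30 splits. A structure of the samples that is not the genotype might give such a count, and this was not tested.

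Striatum PON2-deficient male 5 was the farthest library in striatum, and its deviation from the other libraries falls with transcript length across genes (Spearman rho -0.541 across genes, which are not independent replicates). The median log2 deviation was 0.48 in the shortest genes and -0.49 in the longest genes, which is consistent with a loss of long transcripts such as degraded RNA or a different fragment selection gives. Wild-type male 5 of the same region had a rho of -0.410, so the trend is not particular to 1 genotype. Choroid plexus tissue is argued against, since 5 other striatum libraries have a higher mean of its markers, and so is a wrong label, since Pon2 was 3.67 CPM, Xist 1.14 CPM and Adora2a 226 CPM (the last without TMM scaling). No biological explanation was tested, and the cause of the length trend stays open.

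The genotype effect on the myelin markers in striatum differed between the sexes, a pattern picked out of 105 interaction tests, while within a sex the list did not pass with an estimated correlation (adjusted p = 0.138 in females and 0.0807 in males, or 0.151 with the male pairs as a block). In the model without the male pairs a single library is argued against, since the highest adjusted p with an estimated correlation over the left-out libraries was 0.0380 (without PON2-deficient male 4, and 0.0370 without wild-type male 5). In that model transcript length is argued against too, since the adjusted p was 0.0108 with the length slope added. Neither was tested with the male pairs as a block. The permutation p for the largest difference over all 35 lists, taken times the 3 regions, was 0.0119, and 0.0424 with the assumed male pairs kept together. A chance pattern of library means is thus less likely but not excluded. These values were not adjusted for the other comparisons in which the lists were tested. With the replicate numbers as a block in males the median log2 of the list was 0.42 (median SE 0.131) against 0.44 (0.155) without it. The call with an estimated correlation then ended (adjusted p = 0.0682), where the estimated correlation between the genes was 0.346 against 0.256. Different amounts of white matter in the dissected tissue cannot be told apart from a change in myelin transcripts, since no list measures white matter alone, and of tissue that the same dissection might carry, cortical markers gave 0.678 and thalamic markers, which moved the same way, 0.464 for the interaction (1.71e-05 with the preset correlation), so an effect of genotype that depends on sex stays a hypothesis.

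Among the genes next to Pon2, Asb4 fell in cerebellum, and the list of neighbours was lower in cortex (26 of 31, adjusted p = 0.00277, and adjusted p = 0.138 with an estimated correlation) but did not pass in striatum (0.599) or cerebellum (0.0903). A stretch of chromosome 6 that differs between genotypes is a candidate explanation in cerebellum, where 10 of 34 genes within 5 Mb had an unadjusted p under 0.05, an odds ratio of 3.34 against genes elsewhere (Fisher's exact p = 0.00301). Asb4, whose fall prompted this test, is among these 10 genes. By the same exact test the odds ratio was 2.52 within 10 Mb (exact p = 0.0149), 1.81 within 20 Mb (p = 0.0638) and 0.981 over chromosome 6 (p = 0.915), while within 5 Mb in cortex it was 0.615 (p = 0.620) and in striatum 0.988 (p = 1), which do not decide. Low counts are open, since among genes under 3 CPM 3 of 7 neighbours passed (exact p = 0.0126), too few genes to decide. Reads of Pon2 counted for Pon3 are argued against as the source of the whole fall of Pon3 in cerebellum. At that rate Pon3 would need to fall by 1.51 CPM in striatum, more than its wild-type level of 1.47 CPM, and it fell by 0.0181 CPM (SE 0.200). A smaller share of such reads was not tested. A direct effect of PON2 loss on its neighbours was not tested and stays open beside the linked stretch here.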

How the results depend on the processing

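The transcript length slope, the choroid plexus mean, the robust spread, the block in the males of striatum and leaving out libraries with a length slope under -0.1 were chosen after seeing the data. Of 7746 values of 252 results under alternatives, 7022 were classed as the same, 432 as weaker, 135 as stronger, 148 as moved and 9 as reversed. Those classed as the same include counts of genes and of lists that stayed similar. The class therefore does not mean that each value kept its direction and side of the threshold. Where no cause is named below, the cause was not tested. Pon2 passed in each region under every alternative that was run.

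DESeq2 called 238 genes in cortex, 31 in female cortex, 433 in male cortex, 51 for the cortex interaction and 80 for sex in cortex. In striatum it called 7, 2, 5, 7 and 59, and in cerebellum 244, 8, 203, 1 and 44 for the same comparisons. For the regions it called 7 (striatum minus cortex), 17 (cerebellum minus cortex) and 7 (cerebellum minus striatum). With its calls, 24 genes were shared by cerebellum and cortex, and the test around Pon2 in cortex turned to an excess (exact p = 0.0228).

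limma with quality weights called 34 genes in cortex, 2 in female striatum, 2 in male striatum, 57 for sex in striatum, 23 in cerebellum, 12 in male cerebellum and 12 for cerebellum minus cortex. The deposited values and weights gave 2 in female striatum, 2 in male striatum, 57 for sex in striatum, 18 in cerebellum, 12 in male cerebellum and 12 for cerebellum minus cortex. With a mean CPM of at least 1 the counts were 1 in striatum and 1 for cerebellum minus striatum, since Gm43610 is then not tested. Without the genes within 20 Mb of Pon2 the overlap of calls between regions was 0 for each pair, since Pon2 was the shared gene.

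In 1 fit over all libraries the counts were 2 in cortex, 4 in female cortex, 17 in male cortex, 4 in striatum, 18 in female striatum, 11 in male striatum, 6 for the striatum interaction, 145 for sex in striatum, 13 in cerebellum and 14 in male cerebellum. With 2 surrogate variables they were 5 in male cortex, 10 in cerebellum and 2 in female cerebellum, and the direction reversed for the meningeal list in cortex (adjusted p = 0.0202) and the ribosomal (0.000550) and calcium (0.0487) lists in cerebellum.

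With the length slope in the model the counts were 127 in cortex, 11 for sex in cortex and 7 in male cerebellum. With the choroid plexus mean they were 2 in cortex, 10 for sex in cortex, 9 lists in cortex and 4 lists in cerebellum. The choroid plexus list itself then reversed in cortex (adjusted p = 0.823) and cerebellum (0.817), which the alternative's construction brings about, since it removes that list's own mean. Without the libraries with a low slope the counts were 2 in female striatum, 33 for sex in striatum and 2 in female cerebellum, and the nuclear respiratory list in striatum reversed to lower (adjusted p = 0.000850).

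With an estimated correlation 0 lists passed in cortex, 1 in striatum and 0 in cerebellum, and with fry 1, 1 and 0. In the form of fry for changes in either direction 0, 0 and 8 passed.

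The labels do not say whether equal replicate numbers pair mice. Of the pairs of PON2-deficient and wild-type libraries of 1 number, 3 of 10 in cortex, 6 of 10 in striatum and 2 of 10 in cerebellum correlated above 0.1. In male striatum all 5 did, replicate 5 of both genotypes with a low length slope (-0.104 and -0.335). No correlations of unequal numbers are given, so these values do not show that equal numbers pair the males. In the other groups of region and sex not all pairs were above 0.1. With the block in the males of striatum edgeR called 4 genes over both sexes, and 1 in males and 0 for the interaction as without it, and the heat shock list passed (adjusted p = 0.0405). Between regions, the best match of a library had its own number in 9 of 20 for striatum and cortex, 16 for cerebellum and cortex and 14 for cerebellum and striatum, where chance gives 4. With the replicate number as a block edgeR called 24 genes in cortex, 3 for the cortex interaction, 11 for sex in cortex, 11 in cerebellum and 5 in male cerebellum. With a block for each sex, genotype and number in the fit over the regions it called 4 genes for cerebellum minus cortex and 3 for cerebellum minus striatum.

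With each library left out in turn, counts ranged from 1 to 26 in cortex, 1 to 2 in female cortex, 1 to 150 in male cortex, 0 to 2 for the cortex interaction and 9 to 22 for sex in cortex. In striatum they ranged from 1 to 2 in females and 10 to 25 for sex, and in cerebellum from 1 to 49, 1 to 2 in females and 2 to 41 in males. Region counts ranged from 0 to 2 for striatum minus cortex and 3 to 5 for cerebellum minus cortex. Lists called ranged from 9 to 19 in cortex, 6 to 12 in striatum and 4 to 12 in cerebellum. In striatum the nuclear respiratory list ranged from adjusted p = 1.86e-07 (lower, without PON2-deficient male 5) to 0.623, and the ribosomal list from 7.64e-09 to 0.745 (lower, without PON2-deficient male 5).

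Depth was similar in all libraries, and no test at lower depth was made. Counting error weighs most in genes near 1 CPM or below, such as Asb4, Pon3 and Gm43610. In striatum a 1.2-fold change was recovered in 17.9% of the genes so changed in the simulation over both sexes, all of at least 1 CPM.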
